A study of Mus musculus with 5 samples.

How the data were processed

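Single-cell RNA sequencing measured microglia, the resident macrophages of the brain, from the primary somatosensory cortex (S1) of mice on postnatal day 15. Per the labels' protocols, cells were enriched on a Percoll gradient, stained for Cd11b, CD45 and Cx3cr1, sorted by fluorescence, and made into libraries with the 10x Genomics Chromium 3′ kit, which reads the 3′ end of polyadenylated RNA and marks each molecule with a unique molecular identifier (UMI). Each of the 5 libraries pooled the cells of several mice, so the replicate is a pool and the spread between mice within a pool was not measured. The labels gave 2 wild-type (WT) libraries, 1 library carrying 1 Cx3cr1-Cre allele with intact GABA-B receptor alleles (Cre-Het), and 2 conditional knockout (cKO) libraries carrying the same Cre allele with floxed GABA-B receptor alleles. The sample labels call the receptor alleles of WT mice wild type, whereas the design text of the series calls them floxed, and this was not settled here.

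The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the whole-number values. Cell Ranger 3.0.0 and Seurat, whose version is not stated, are named with the builds GRCm38 and mm10 in the submitters' processing notes. The annotation release, the alignment settings and the filter that selected the deposited barcodes are not given in the sources used here. Every deposited barcode had at least 500 UMIs, as tested on the files. The matrices list 31053 genes, of which 71 share their symbol with another gene, so genes were joined by their Ensembl identifiers. Positions came from the GENCODE vM21 annotation of GRCm38, which holds 30934 of these identifiers.

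Cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 23353 of 29378 barcodes. Scrublet, run through scanpy, marked 49 doublets in WT 1, 4 in WT 2, 2 in cKO 1 and 0 in the Cre-Het and cKO 2 libraries. A library with under 0.5% marked cells was taken as one in which the caller had not worked, which held for every library except WT 1, where 2.84% were marked. Loading alone would give an expected 1.61% in WT 1, 3.38% in WT 2, 10.7% in Cre-Het, 2.81% in cKO 1 and 4.99% in cKO 2. Clusters led by markers of more than 1 cell type were looked for instead. Of 21 clusters, 1 neutrophil cluster also had a monocyte marker among its leading genes, and 0 had several markers of each of the types. The marked cells were left out in every library. Doublets between microglia that were not marked therefore stayed in.

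The 23298 cells kept were clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method of igraph 0.11.9 at a resolution of 0.6. Clusters were named from markers fixed beforehand. Microglial clusters held 23144 cells, or 99.3%, and 148649355 of the 161106275 deposited UMIs. No microglial cluster had 100 cells in every library, and the genes that define the clusters differ between the groups, so shares of microglia per cluster were not compared. A further clustering on genes centred and scaled within each library, chosen after seeing the data, gave 15 clusters, and the 3 with at least 100 cells in every library were used for tests within a microglial state.

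The raw counts of all microglia were summed per library and tested with edgeR 4.0.16. One quasi-likelihood fit over the 5 libraries and 3 groups gave each contrast, after TMM scaling and edgeR's own expression filter, which kept 13165 genes. The fit had 2 residual degrees of freedom and 5.03 prior degrees of freedom, with a biological coefficient of variation of 0.0913. The Cre-Het group has 1 library, so it is assumed to vary as the other groups do. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene is said to have changed at an adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) of the fit. A ratio against a group with 0 UMIs is a lower bound computed with 3 UMIs over that group, and with 1 to 3 UMIs it is given with its 95% exact interval, which covers counting error only. Such ratios without single libraries were added after the data were seen.

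The genes named were set by a rule. For each contrast it took Gabbr1, Gabbr2 and Cx3cr1. It took the 10 highest and 10 lowest genes by log2 fold change among those that changed, had a mean of at least 5 CPM (counts scaled to equal library totals) and did not overlap between the libraries of the groups. It took the members of each described list with the smallest p, and the 10 genes with the smallest p that changed the same way against both control groups. Unnamed gene models were counted but not named by this rule, and a few genes within the rule are not reported here. Before the data were examined, 22 gene lists and 19 lists of cell-type and microglial-state markers were fixed. All markers of the interferon-responsive, cycling, chemokine-rich, axon-tract and homeostatic states also belong to a longer gene list. So do the measured markers of dissociation-activated microglia, which are all on the list of immediate early genes. Counts and calls of these states therefore repeat part of that list and are not independent of it. The 37 lists with at least 3 measured genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over these lists, and again with an estimated correlation and with fry. A list of p53 target genes was added after a cluster led by such genes had been seen, and no test of that list is given.

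To compare shares of cells with a Gabbr1 or Gabbr2 UMI, each microglial cell was thinned to 2000 UMIs and shallower cells were left out, 115 in WT 1, 133 in WT 2, 825 in Cre-Het, 132 in cKO 1 and 180 in cKO 2. Shares have 95% Clopper-Pearson intervals, a share of 0 has the limit of 3 cells over the total, and they were compared with two-sided exact permutation tests over libraries. The smallest p is 0.333 for 2 against 2 libraries and 0.1 for 2 against 3. Sex was read per cell from UMIs of Xist and of Y-linked genes. Of the microglia, 12962 had UMIs of Xist alone, 6855 of Y-linked genes alone, 908 of each and 2419 of neither. Cells with UMIs of each numbered 20 in WT 1, 35 in WT 2, 654 in Cre-Het, 121 in cKO 1 and 78 in cKO 2. Whether these cells are doublets was not tested.

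Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 15.7 between the WT libraries and 15.2 between the cKO libraries, so none was treated as a second copy of another. Each pool counted as a replicate by the design. The test was run on simulated counts with 200 genes changed 2-fold, drawn 8 times from the real means and library sizes. With a spread that follows the fitted trend, it recovered 78% of the changed genes for cKO against WT (12906 genes), 73.1% for cKO against Cre-Het (12901 genes) and 74.9% for Cre-Het against WT (12905 genes). Unchanged genes made up 2.5%, 5% and 4% of the calls. With a spread that varies gene by gene, the recovered shares were 75.8% (12906 genes), 70.7% (12910 genes) and 73.3% (12912 genes), and unchanged genes made up 13.7%, 15.8% and 14.5% of the calls, above the nominal 5%. For the test of cells with against cells without a Gabbr1 UMI, 1 draw over 9645 genes recovered 76%, with 3.2% of the calls on unchanged genes.

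Alternatives set in advance were DESeq2 1.42.0, the size factors of DESeq2, no expression filter, all cells, doublets kept, the largest microglial cluster alone, a stricter filter of 2000 UMIs and 5% mitochondrial UMIs, equal cells and UMIs per library (1562 cells each), female or male cells alone, the labelled male share of the pool as a covariate, the controls pooled, a replicate block, and each library left out in turn. Chosen after seeing the data were the measured male share as a covariate, the low-UMI clusters left out, and the interferon, cycling, p53 and low-UMI clusters left out (together called the state clusters). Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.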

Results

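Microglia sorted from the S1 cortex of 15-day-old mice were measured by single-cell RNA sequencing in 2 WT, 1 Cre-Het and 2 cKO libraries. The 5 libraries held 29378 barcodes, with 2011 in WT 1, 4224 in WT 2, 13391 in Cre-Het, 3515 in cKO 1 and 6237 in cKO 2. Total UMIs were 10428947, 26313528, 61548506, 22778292 and 40037002 in the same order. The pools came from 35 mice: 2 females and 2 males in WT 1, 1 female and 7 males in WT 2, 8 females and 2 males in Cre-Het, 3 females and 3 males in cKO 1, and 6 females and 1 male in cKO 2, as labelled. The cell filter passed 85.9% of the barcodes in WT 1, 89.2% in WT 2, 69.8% in Cre-Het, 86.5% in cKO 1 and 87.8% in cKO 2. Microglia numbered 1677, 3745, 9256, 3011 and 5455, with median depths of 6049, 6838, 5376, 7060 and 7062 UMIs. Their median mitochondrial share was highest in Cre-Het, at 4.52%, against 3.48% in WT 1, 2.56% in WT 2, 3.29% in cKO 1 and 2.78% in cKO 2.

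Other cells were few. Border-associated macrophages, which line vessels and meninges, numbered 1 in WT 1, 7 in WT 2, 27 in Cre-Het, 8 in cKO 1 and 6 in cKO 2. Monocytes numbered 0, 11, 22, 2 and 7, and neutrophils 0, 1, 40, 17 and 5 in the same order. The groups' microglia lay mostly in different clusters. Cluster 2 held most cells of WT 1 (1132) and WT 2 (2772), cluster 1 most cells of cKO 1 (1602) and cKO 2 (3146), and clusters 3 and 4 together most of Cre-Het (3933 and 3501). Values within microglia below therefore compare groups whose cells lie mostly in different clusters.

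The targeted gene, Gabbr1, encodes the ligand-binding subunit of the GABA-B receptor, the metabotropic receptor for the inhibitory transmitter GABA (ENSMUSG00000024462, chromosome 17, 37045966 to 37075067, GRCm38). In microglia it stood at 38.5 CPM in WT 1, 47.1 in WT 2, 52.2 in Cre-Het, 34.8 in cKO 1 and 34.9 in cKO 2. The cKO libraries were below every control library, by a log2 fold change of -0.31 (SE 0.11) against WT, which did not pass the test (adjusted p = 0.213), and of -0.58 (SE 0.12) against Cre-Het, which did (adjusted p = 0.0272). The labels do not give the floxed exons, and a 3′ tag outside the deleted part would still be counted, so these levels do not measure how many cells lost the receptor. Gabbr2, the partner subunit, did not pass the expression filter. Cx3cr1, the fractalkine receptor whose locus carries Cre (chromosome 9, 119901616 to 120069879), stood at 7202 and 6663 CPM in the WT libraries, 3260 in Cre-Het, and 3381 and 2950 in the cKO libraries. It fell by 1.13 on the log2 scale in cKO against WT (SE 0.09) and by 1.09 in Cre-Het against WT (SE 0.11), while cKO against Cre-Het was -0.04 (adjusted p = 0.812).

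**Figure D1:**
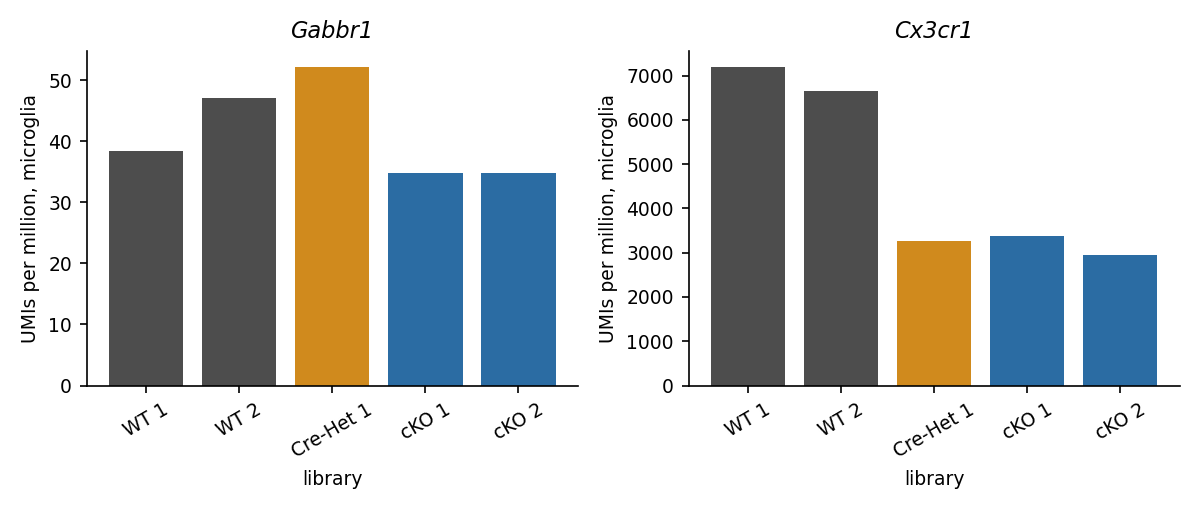
Bars give Gabbr1 (left) and Cx3cr1 (right) in CPM over all microglia of each library, with 1 bar per library and no error bar. Cx3cr1 stood at 7202 and 6663 in the WT libraries and at 3381 or below in the 3 libraries that carry Cre.

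At 2000 UMIs per cell, the share of microglia with a Gabbr1 UMI was 7.11% in WT 1 (5.88 to 8.50), 9.44% in WT 2 (8.51 to 10.4), 10.4% in Cre-Het (9.77 to 11.1), 6.95% in cKO 1 (6.05 to 7.94) and 5.74% in cKO 2 (5.13 to 6.41). The mean was 6.35% ± 0.851 in cKO and 8.27% ± 1.65 in WT (SD, n = 2 each), a difference of -1.93 percentage points (exact permutation p = 0.333, the smallest this design allows). For the share of microglia with a Gabbr1 UMI, cKO minus WT, percentage points were -0.761 without WT 2, -3.10 without WT 1, -2.53 without cKO 1, -1.33 without cKO 2 and -1.23 at 1000 UMIs. Against the 3 control libraries together the difference was -2.64 points (exact permutation p = 0.2). It was -1.61 points at 1000 UMIs (exact permutation p = 0.1, the smallest this design allows) and -2.54 without thinning (exact permutation p = 0.5). Without thinning the shares were 18.8%, 26.5%, 24.6%, 20.1% and 21.5%, and cKO minus WT was -1.91 points. As a background, 1 of 46 border-associated macrophages (2.17%), 0 of 42 monocytes, which allows up to 7.14%, and 2 of 59 neutrophils (3.39%) had a Gabbr1 UMI at the same depth. A Gabbr2 UMI was found in 0 thinned cells of WT 1, 2 of WT 2, 3 of Cre-Het, 1 of cKO 1 and 1 of cKO 2, too few to compare.

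The comparison of cKO with WT asks how microglia differ when they carry Cre and floxed receptor alleles. Interferon-response genes, which cells turn on after type I interferon, were many times higher in both cKO libraries. Ifi27l2a was 13.1 and 15.2 CPM in the WT libraries and 276.6 and 351.2 in the cKO libraries, a log2 fold change of 4.45 (SE 0.15, n = 2 each). Cxcl10, a chemokine that draws T cells, rose by 6.73 (SE 0.23), and Cxcl9, a related chemokine, had 1063 UMIs in cKO and 0 in WT, at least 204-fold higher, 101-fold without cKO 2 and 55.0-fold without WT 2. Of 35 cell-cycle genes 30 also rose, and of 20 antigen-presentation genes 8. Of 13165 genes, 335 rose and 75 fell (edgeR), with 2105 at an unadjusted p under 0.05.

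All 25 measured interferon-response genes rose, with a median log2 fold change of 3.23, and the same 25 when adjusted over the list alone. Besides Ifi27l2a and Cxcl10, Ifit3, which binds foreign RNA together with Ifit1, rose by 3.23 (SE 0.12), and Usp18, which dampens interferon signalling, by 3.62 (SE 0.16). The call of the list by camera was lost with an estimated correlation (adjusted p = 0.154), while fry stayed just under the threshold (adjusted p = 0.0498). All 12 markers of an interferon-responsive microglial state rose, with a median of 3.54 (adjusted p = 0.153 with an estimated correlation). These markers all belong to the interferon-response list, so their count follows from it. Among the 10 genes with the largest rise, of those with a mean of at least 5 CPM and no overlap between libraries of the groups, were also Ccl5, a T-cell chemokine (6.38, SE 0.52), Oas1a, a sensor of double-stranded RNA (4.15), Ifit1 (3.93) and Ifi44l (3.80). Ifi202b (4.55) and Ifi204 (3.75) belong to a family of near-identical genes between which reads can be split, so their values are uncertain. In antigen presentation 8 of 20 genes rose and 0 fell, 15 when adjusted over the list alone, with a median of 0.84 (adjusted p = 0.193 with an estimated correlation). H2-D1 rose by 1.98 (SE 0.11), H2-K1 by 1.69 and H2-Q7 by 2.10, class I genes that are polymorphic and alike and therefore uncertain. Tap1, which carries peptides to class I molecules, rose by 0.86.

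Of 35 cell-cycle genes 30 rose, 33 when adjusted over the list alone, with a median of 2.09 (adjusted p = 0.188 with an estimated correlation). Stmn1, which destabilises microtubules, rose by 1.45 (SE 0.08), Birc5, an inhibitor of apoptosis active at mitosis, by 2.73, Hmgb2 by 0.95 and the cyclin Ccnb2 by 2.62. Among markers of cycling microglia, which all belong to the cell-cycle list, 11 of 12 rose, with a median of 2.17 (adjusted p = 0.182 with an estimated correlation). In the added list of p53 targets, genes that p53 turns on after DNA damage, 10 of 30 rose, with a median of 0.43. This list was chosen because such genes led a cluster, cluster 7, of these cells, so its counts are not independent evidence and no test of the list is given. Phlda3 rose by 4.60, Cdkn1a, which halts the cell cycle, by 2.63, Psrc1 by 4.10 and the apoptosis gene Bbc3 by 1.42. Without the state clusters 2 cell-cycle genes rose, with a median of 0.37, and 2 p53 targets, with a median of 0.15, while 19 interferon-response genes rose, with a median of 2.52. The clusters left out were picked by genes of these same kinds, so lower counts follow in part from that choice. In cKO against WT the cell-cycle count was also lower without cKO 1 (13), cKO 2 (18) or WT 2 (20), at equal depth (14), and in female (5) and male (9) cells alone, with medians between 1.39 and 2.12.

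Of 26 NF-kB cytokines and chemokines 7 rose, 11 when adjusted over the list alone, with a median of 0.23 (adjusted p = 0.168 with an estimated correlation). The chemokines Ccl12 and Ccl2 rose by 2.16 (SE 0.10) and 2.91, and the cytokines Il6 and Il1b by 1.53 and 2.53. In the chemokine-rich microglial state 4 of 11 markers rose (adjusted p = 0.168 with an estimated correlation). Of 22 genes of developmental axon-tract and disease-associated microglia 3 rose: Axl, a receptor for dying cells (3.12, SE 0.20), Csf1, the growth factor of microglia (0.87), and Spp1, osteopontin (1.51). Adjusted over the list alone, 6 rose and 3 fell, and the list's adjusted p was 0.762 with an estimated correlation. Of 9 markers of the axon-tract state 2 rose, Csf1 and Spp1 (adjusted p = 0.621 with an estimated correlation). Of 20 cholesterol-synthesis genes 2 rose, 3 when adjusted over the list alone, among them Sqle (0.91), with an adjusted p = 0.374 for the list with an estimated correlation. Of 82 ribosomal protein genes 3 rose, Rps27l, Rpl32 and Rpl37a, by 0.43, 0.34 and 0.34, and 39 when adjusted over the list alone (median 0.19, adjusted p = 0.188 with an estimated correlation). In nuclear-encoded oxidative phosphorylation 0 of 45 genes changed, also when adjusted over the list alone, although camera called the list higher (median 0.13, adjusted p = 0.621 with an estimated correlation).

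Of the 75 genes that fell in cKO, the 10 with the largest fall under the same conditions included Efnb2, a membrane-bound ephrin (-1.78, SE 0.24). Also among them were Hlf, a clock-related transcription factor (-1.57), the phosphatase Ptprm (-1.40), Dlc1 (-1.32), Hif3a (-1.31), the sulfotransferase Sult1a1 (-1.24), Mdfi (-1.23), the junction protein Jam3 (-1.22) and Cx3cr1 (-1.13). Camera called homeostatic microglial genes lower (median -0.12), although 1 of 20 fell, 3 when adjusted over the list alone. That gene was Cst3, cystatin C, at -0.48 (adjusted p = 0.667 for the list with an estimated correlation). Of 10 general microglia markers 1 fell, Cx3cr1, and 2 when adjusted over the list alone (adjusted p = 0.621 with an estimated correlation).

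Some genes on the marker lists of other cell types moved within microglia, which alone does not show a change in those cells. Of 4 astrocyte markers 2 fell, among them the glutamate transporter Slc1a3 (-0.72), with a median of -0.68 (adjusted p = 0.275 for the list with an estimated correlation). Slc1a3 stood at 328.7 and 281 CPM in the WT libraries, while Slc1a2 and Aldoc were under 1 CPM in every library. Of 8 monocyte markers 2 rose, Ms4a4c (2.24) and Plac8 (1.90), with an adjusted p = 0.352 for the list with an estimated correlation. Monocytes themselves numbered 2 and 7 in the cKO libraries, beside 0 and 11 in the WT libraries. Of 8 neutrophil markers 0 changed and 2 passed when adjusted over the list alone (adjusted p = 0.621 with an estimated correlation). S100a8 had 294 UMIs in cKO and 1 in WT, a ratio of 169 (30.1 to 6700), and S100a9 336 and 1, a ratio of 193 (34.4 to 7654). Camp was at least 13.4-fold and Ngp at least 10.2-fold higher. Most of these UMIs came from cKO 1, and without it the ratios were 45.2 for S100a8 (7.75 to 1819) and 49.6 for S100a9 (8.55 to 1994), with bounds of 3.84 for Camp and 2.66 for Ngp. Without cKO 2 the ratios were 398 for S100a8 (70.8 to 15790) and 458.6 for S100a9 (81.65 to 18180). The bounds were then 31.1 for Camp and 24.0 for Ngp. Without WT 2 the bounds were 15.2 for S100a8, 3.62 for Camp and 2.74 for Ngp, and the ratio for S100a9 was 52.2 (9.305 to 2068). Without WT 1 the bound for S100a9 was 47.0. Haemoglobin genes differed between libraries of 1 group, with Hbb-bs at 0 CPM in WT 1, 435.1 in WT 2, 276.6 in Cre-Het, 0.42 in cKO 1 and 4.15 in cKO 2, and 0 of 5 erythroid markers changed, while 5 were lower when adjusted over the list alone.

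The remaining preset lists were not called by camera. Of 30 complement and engulfment genes 2 rose, Axl and the complement gene C4b (2.68), and the adhesion receptor Adgrg1 fell by 0.34. In extracellular matrix and adhesion 1 of 28 genes rose, Sdc3, a syndecan (2.83). In synapse organisation and signalling to neurons 2 of 22 rose, the semaphorin receptor Nrp1 (1.04) and Tnf (1.25), and 1 fell, Cx3cr1. In neurotransmitter receptors 1 of 12 fell, the adrenergic receptor Adrb1 (-0.65), in cAMP targets 1 of 15 rose, the phosphodiesterase Pde4b (1.10), and in immediate early genes 1 of 25 rose, Klf2 (1.06). None of 32 lysosomal, 15 heat-shock, 16 glycolytic, 18 lipid-handling, 15 TGF-beta and 13 mitochondrially encoded genes changed (edgeR). Nor did any of 10 sex-chromosome genes, 6 border-associated macrophage, 8 neuronal and 5 oligodendrocyte markers, 10 markers of dissociation-activated and 9 of homeostatic microglia. Adjusted over the list alone, 1 lysosomal gene, 4 border-associated macrophage markers and 1 oligodendrocyte marker were higher, and 1 lipid-handling gene, 2 sex-chromosome genes, 1 border-associated macrophage marker and 1 neuronal marker were lower. Of 6 endothelial markers 1 fell, the adhesion molecule Pecam1 (-0.76).

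Without WT 2, cKO 1 or cKO 2 the comparison of cKO with WT gave 251, 224 and 229 genes in place of 410. It gave 1243 with no expression filter, 196 at equal depth, 135 in female and 134 in male cells, 144 and 106 with the labelled and measured male share as a covariate, 131 without the state clusters, 11 in the largest cluster, and 9 with Cre-Het pooled with WT.

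**Figure D2:**
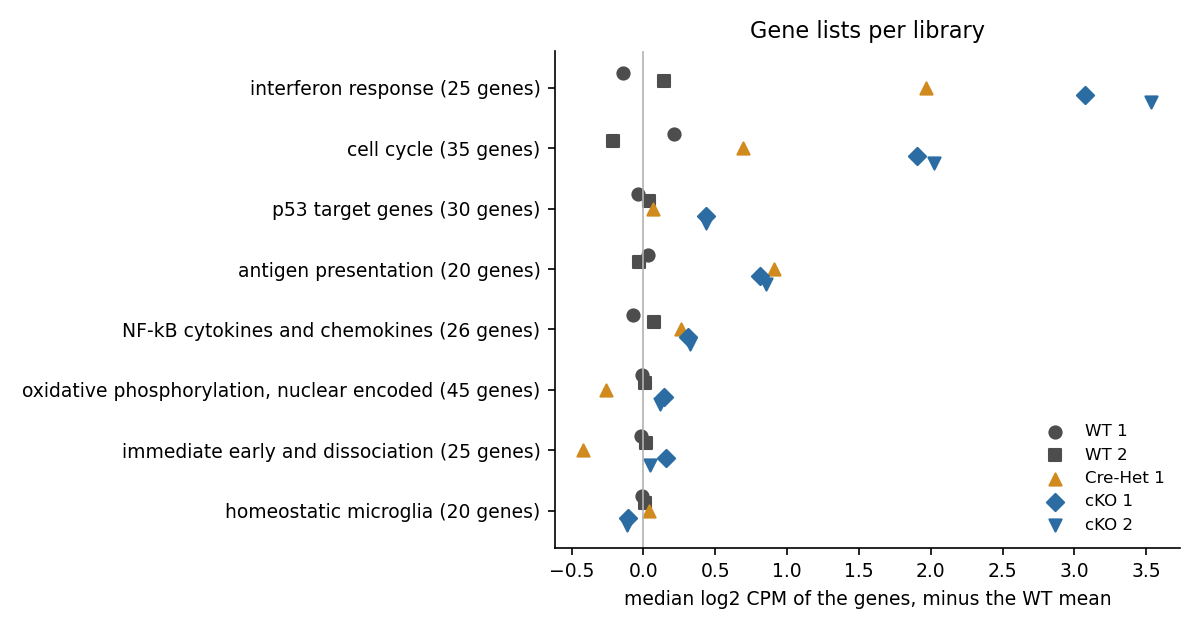
Each point is 1 library's median log2 CPM over the genes of a list, minus the mean of the WT libraries (horizontal axis), for 8 lists (vertical axis, with the number of genes measured). Interferon-response genes stood at 3.07 and 3.54 in the cKO libraries and at 1.97 in Cre-Het, and cell-cycle genes at 1.90 and 2.02 in cKO and 0.69 in Cre-Het.

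Within the larger clusters of the clustering centred by library, 163 genes changed between cKO and WT in cluster 1 (6896 cells), 100 in cluster 2 (6843 cells) and 9 in cluster 3 (3783 cells). Cluster 3 had a median of 3417 UMIs per cell, beside 7027.5 and 7218, with mitochondrial genes and Nrp1, Spint1 and Csmd3 among its leading genes. It held 30.5% of Cre-Het microglia and 3.70 to 18.2% of those of the other libraries, so a state and lower RNA quality were not told apart in it. Ifi27l2a rose by 4.63, 4.57 and 4.72 in these clusters, and Cdkn1a by 2.08, 1.91 and 2.67. Interferon-response genes had medians of 2.99, 3.14 and 2.32, with 17 of 23, 16 of 24 and 5 of 15 measured genes past the threshold. Stmn1 did not pass it in any of the 3, at 0.12, 0.37 and 0.63. Leaving out single libraries moved the counts, in cluster 1 to 270 without cKO 1 and 86 without cKO 2, in cluster 2 to 245 and 222, and in cluster 3 to 19 without WT 1 and 66 without WT 2.

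The comparison of cKO with Cre-Het, where all libraries carry Cre, sets floxed beside intact receptor alleles, as labelled. Of 25 interferon-response genes 20 rose and of 35 cell-cycle genes 17, with an adjusted p = 0.379 for each list with an estimated correlation. Cxcl10 rose by 2.82 (SE 0.17) and Ifi27l2a by 2.10 (SE 0.16; 2 libraries against 1). Of 82 ribosomal protein genes 53 rose and of 45 oxidative phosphorylation genes 31 (adjusted p = 0.379 each with an estimated correlation), while single genes such as Nrp1 (-3.58, SE 0.11) and Spint1, a protease inhibitor, were far lower. Of 13165 genes, 943 rose and 899 fell (edgeR), with 4223 at an unadjusted p under 0.05. The Cre-Het cells also had the highest mitochondrial share, 4.52%, and the lowest median depth, 5376 UMIs.

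Of 25 interferon-response genes 20 rose and 0 fell, also 20 when adjusted over the list alone, with a median of 1.27 (adjusted p = 0.379 with an estimated correlation). Ifit3 rose by 1.27 and Usp18 by 1.49. Of 35 cell-cycle genes 17 rose, 32 when adjusted over the list alone, with a median of 1.24 (adjusted p = 0.379 with an estimated correlation). Stmn1 rose by 1.03, Birc5 by 1.54 and Ccnb2 by 1.86. Of the added p53 targets 7 of 30 rose, among them Cdkn1a (2.07), Phlda3 (1.88) and Psrc1 (2.04). Of 82 ribosomal protein genes 53 rose, 69 when adjusted over the list alone, with a median of 0.38, among them Rpl31 (0.69) and Rps20 (0.60), and of 45 oxidative phosphorylation genes 31 rose, 41 when adjusted over the list alone, with a median of 0.39, among them Uqcrq (0.60) and Cox5b (0.59). Each of these lists had an adjusted p = 0.379 with an estimated correlation. In cKO against Cre-Het fewer genes passed without 1 of the cKO libraries. Without cKO 1 the counts were 13 interferon-response, 6 cell-cycle, 5 ribosomal and 0 oxidative phosphorylation genes (edgeR), and without cKO 2 they were 12, 6, 19 and 12, with medians of 1.13 and 1.15, 1.19 and 1.16, 0.39 and 0.36, and 0.37 and 0.40. The cell-cycle count was 31 without WT 1 and 28 without WT 2, which enter only the shared spread. With the stricter cell filter 13 interferon-response, 9 cell-cycle, 8 ribosomal and 1 oxidative phosphorylation genes rose. Without the state clusters 10 interferon-response genes (median 0.56) and 1 cell-cycle gene rose, and camera no longer called the cell cycle (median 0.11, adjusted p = 0.21). Those clusters were picked by such genes, so this drop follows in part from the choice.

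In NF-kB cytokines and chemokines 8 of 26 genes rose and 1 fell (adjusted p = 0.379 with an estimated correlation), among them Ccl12 (1.45), Il1b (1.89) and Tnf (1.44). In immediate early genes, which respond within minutes to stimuli and to tissue dissociation, 6 of 25 rose, among them Klf2 (1.59), Jund (0.66) and Junb (1.06), 7 when adjusted over the list alone (adjusted p = 0.452 with an estimated correlation). In cholesterol synthesis 5 of 20 rose, among them Fdps (0.80) and Stard4 (0.98), 8 when adjusted over the list alone (adjusted p = 0.379 with an estimated correlation). In glycolysis 3 of 16 rose, Gpi1 (0.42), Gapdh (0.47) and Pkm (0.36), 7 when adjusted over the list alone (adjusted p = 0.530 with an estimated correlation). Markers of the cycling (7 of 12), interferon-responsive (10 of 12) and chemokine-rich (5 of 11) states rose, each list with an adjusted p = 0.379 with an estimated correlation, and 3 of 10 markers of dissociation-activated microglia rose, Junb, Jun (0.90) and Fos (3.59), with an adjusted p = 0.591. The measured markers of these states all belong to lists counted above, with Junb, Jun and Fos among the immediate early genes. Their counts are therefore not independent of those lists.

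Among complement and engulfment genes 1 of 30 rose and 8 fell, 13 lower when adjusted over the list alone, with a median of -0.26 (adjusted p = 0.607 with an estimated correlation). The integrin Itgav was at -0.81, Adgrg1 at -0.56 and Sirpa, a receptor for the signal Cd47 on healthy cells, at -0.55. In synapse organisation 1 of 22 rose, Tnf, and 6 fell, among them Nrp1, the scaffold gene Dlg4 (-0.93) and Sema4d (-0.46), with an adjusted p = 0.538 with an estimated correlation. Of 20 homeostatic genes 3 fell, the fructose transporter Slc2a5 (-1.83), Fcrls (-0.49) and Selplg (-0.33), and Sparc rose by 0.44 (adjusted p = 0.607 with an estimated correlation), and of 9 markers of the homeostatic state 2 fell, Slc2a5 and Selplg (adjusted p = 0.530 with an estimated correlation). Camera called neutrophil and erythroid markers lower (adjusted p = 0.624 each with an estimated correlation). Of 8 neutrophil markers 0 changed, with S100a8 at 1214 UMIs in Cre-Het and 294 in cKO, and of 5 erythroid markers 1 fell, Hbb-bt (-7.33).

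Among genes with a mean of at least 5 CPM and no overlap between libraries of the groups, the largest rises were in Gcm1, a transcription factor (5.75, SE 0.74), Ica1l (4.06, SE 0.40), the histone genes Hist1h2ap (3.95), Hist1h3e (3.15), Hist2h2aa1 (2.78), Hist1h4d (2.61), Hist1h2ae (2.34) and Hist1h4h (2.33), Cxcl10 and the galectin Lgals1 (2.43). Replication-dependent histone genes are near-identical and mostly lack poly(A) tails, so their counts are uncertain. Spint1 had 3080 UMIs in Cre-Het and 1 in cKO, a ratio of 3555 (638 to 140500), which was 2307 (413.7 to 91150) without cKO 1 and at least 416 without cKO 2. Other large falls were in Trim30d (-4.45) and Trim12a (-4.41), members of a family of alike genes and therefore uncertain, Nrp1, Csmd3 (-2.76), Hpgd, which breaks down prostaglandins (-2.71), Rnaset2b (-2.53), Ptprm (-2.40) and Mid1 (-2.13). Without cKO 1 or cKO 2 the count of 1842 dropped to 242 and 665. It was 581 with the stricter filter, 1024 at equal depth, 3242 with no expression filter, 452 in female and 643 in male cells, 105 with the measured male share as a covariate, and 1 in the largest cluster.

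Changed the same way against both WT and Cre-Het were 214 genes, 178 higher and 36 lower in cKO. The 10 with the smallest p were Hist1h2ae (1.86 against WT), Cxcl10, Ifi27l2a, Ccl12, Cdkn1a, the copper carrier Cp (2.72 against WT and 2.76 against Cre-Het), Klf2, Stmn1, Ifit3 and Usp18, and each was higher in both cKO libraries than in the 3 control libraries. Independent lists of these sizes would share 24 higher and 5.12 lower genes. In 20 simulations of unchanged groups with the same shared libraries, the mean was 0.8 higher genes (at most 3) and 1 lower gene (at most 3). Because no gene was changed in them, these simulations do not measure the overlap that shared libraries give between lists of these sizes. The cKO libraries enter both comparisons, so part of the excess may come from them. The count was 52 without cKO 1, 85 without cKO 2, 116 with the stricter filter, 80 at equal depth and with the labelled male share, 24 with the measured male share, 35 in female and 56 in male cells, 46 without the state clusters, 704 with no expression filter, and 0 in the largest cluster (edgeR).

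The comparison of Cre-Het with WT sets the library carrying Cre beside WT. It does not isolate the Cre allele, since Cre-Het is 1 pool with another sex mix and a higher mitochondrial share, and the receptor alleles of WT were not settled. In the Cre-Het library 23 of 25 interferon-response and 10 of 20 antigen-presentation genes rose, and Cx3cr1, at the locus of the Cre insertion, was lower. Ifi27l2a, at 73.3 CPM, rose by 2.35 (SE 0.16) and H2-D1 by 1.89 (SE 0.12; 1 library against 2). Of 13165 genes 391 rose and 209 fell (edgeR), with 3175 at an unadjusted p under 0.05. Of 25 interferon-response genes 23 rose and 0 fell, 25 when adjusted over the list alone, with a median of 1.90 (adjusted p = 0.387 with an estimated correlation). All 12 markers of the interferon-responsive state, which belong to that list, rose (adjusted p = 0.387 with an estimated correlation). Ifit3 rose by 1.96, Cxcl10 by 3.92, and Slfn2, which is induced by interferon, by 1.98. At equal depth 12 interferon-response genes rose in Cre-Het against WT (median 1.52), in female cells 15 and in male cells 10. In antigen presentation 10 of 20 genes rose, 14 higher and 1 lower when adjusted over the list alone, with a median of 0.88 (adjusted p = 0.451 with an estimated correlation). H2-K1 rose by 1.66 and the class II chaperone gene H2-DMb1 by 2.94.

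Of 35 cell-cycle genes 3 rose, the helicase genes Mcm3 (0.60) and Mcm6 (1.37), and Birc5 (1.19), 7 when adjusted over the list alone (adjusted p = 0.580 with an estimated correlation). Of 12 markers of cycling microglia 1 rose, Birc5 (adjusted p = 0.580 with an estimated correlation). Of the 30 added p53 targets 2 rose, Phlda3 (2.72) and Psrc1 (2.06). Of 30 complement and engulfment genes 4 rose, Axl (2.75), Itgav (0.64), C4b (2.39) and the complement receptor C5ar1 (0.74), 5 when adjusted over the list alone (adjusted p = 0.580 with an estimated correlation). Of 28 matrix and adhesion genes 4 rose, among them Sdc3 (2.28) and Itga9 (0.65), 7 when adjusted over the list alone (adjusted p = 0.621 with an estimated correlation). Lower were immediate early genes, where 1 of 25 fell, Jund (-0.61), with a median of -0.48 (adjusted p = 0.580 with an estimated correlation), and markers of dissociation-activated microglia, of which 0 of 10 changed (adjusted p = 0.621 with an estimated correlation). Camera also called oxidative phosphorylation lower, where 2 of 45 genes fell, Cox6b1 (-0.42) and Uqcrq (-0.44), 23 when adjusted over the list alone (median -0.26, adjusted p = 0.580 with an estimated correlation). Of 82 ribosomal protein genes 2 fell, Rpl31 (-0.47) and Rpl23a (-0.38), with a median of -0.17 (adjusted p = 0.451 with an estimated correlation). Beside these, 0 of 13 mitochondrially encoded genes changed, with a median of 0.39, although camera called the list higher (adjusted p = 0.714 with an estimated correlation).

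Neutrophil markers rose in 2 of 8 cases, 7 when adjusted over the list alone (adjusted p = 0.580 with an estimated correlation). S100a9 had 1263 UMIs in Cre-Het microglia and 1 in WT, a ratio of 838 (150 to 33130), and S100a8 1214 and 1, a ratio of 806 (144 to 31850), beside 40 neutrophils in Cre-Het, 0 in WT 1 and 1 in WT 2. Without WT 2 the ratio for S100a9 was 226.5 (40.6 to 8952) and the bound for S100a8 72.6, and without WT 1 the bound for S100a9 was 203.9 and the ratio for S100a8 588 (105.3 to 23240). Cxcl9 was at least 54.0-fold higher in Cre-Het, 39.4-fold without WT 1 and 14.6-fold without WT 2. Among genes with a mean of at least 5 CPM and no overlap between libraries, other large rises were in Ccl5 (5.23), Trim30d (5.11), Nrp1 (4.61, SE 0.13), Cxcl10, Trim12a (3.47), H2-Q7 (3.45) and Ifi204 (3.23). Among the largest falls under these conditions were those of Gcm1 (-6.09, SE 0.74), Ica1l (-4.21), the inhibitory receptor Pirb (-2.39), Hist1h3e (-2.34), Hist1h4d (-2.26), the scavenger receptor Colec12 (-2.03), Hist1h4h (-1.89), Olfr1033 (-1.64) and Nbl1 (-1.48). As above, values of the Trim, H2, Ifi2 and histone families are uncertain. Shared with cKO against WT were 101 higher and 15 lower genes, beside 9.95 and 1.19 for independent lists and simulated means of 0.9 (at most 5) and 0.6 (at most 3). As no gene was changed in the simulations, their means do not measure the overlap that shared libraries give between lists of these sizes. The WT libraries enter both comparisons, so part of that excess may come from them. Without WT 2 or cKO 1 the count of 600 dropped to 254 and 356. It was 259 with the stricter filter, 381 at equal depth, 198 in female and 179 in male cells, 63 and 327 with the labelled and measured male share as a covariate, 1998 with no expression filter, and 1 in the largest cluster.

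The share of male cells, among microglia with UMIs of either Xist or Y-linked genes, was 40.0% in WT 1 (37.4 to 42.7), 16.0% in Cre-Het (15.2 to 16.8) and 38.6% in cKO 1 (36.7 to 40.5), against 50%, 20% and 50% male mice in the labelled pools. It was 5.05% in WT 2 (4.36 to 5.82), labelled with 87.5% male mice, and 90.7% in cKO 2 (89.8 to 91.6), labelled with 14.3%. The sex labels of WT 2 and cKO 2 were therefore not used, except in the covariate set in advance. Microglia with UMIs of neither kind are left out of the measured shares. They numbered 288 in WT 1, 88 in WT 2, 580 in Cre-Het, 332 in cKO 1 and 1131 in cKO 2. The intervals cover counting error only, not cells whose sex was missed. In female cells alone interferon-response genes had a median of 3.26 in cKO against WT, with 22 of 25 past the threshold, and in male cells alone 3.17, with 18. The change in cKO against WT differed between male and female cells for 1 gene, Hbb-bs (edgeR, 442 at an unadjusted p under 0.05).

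**Figure D3:**
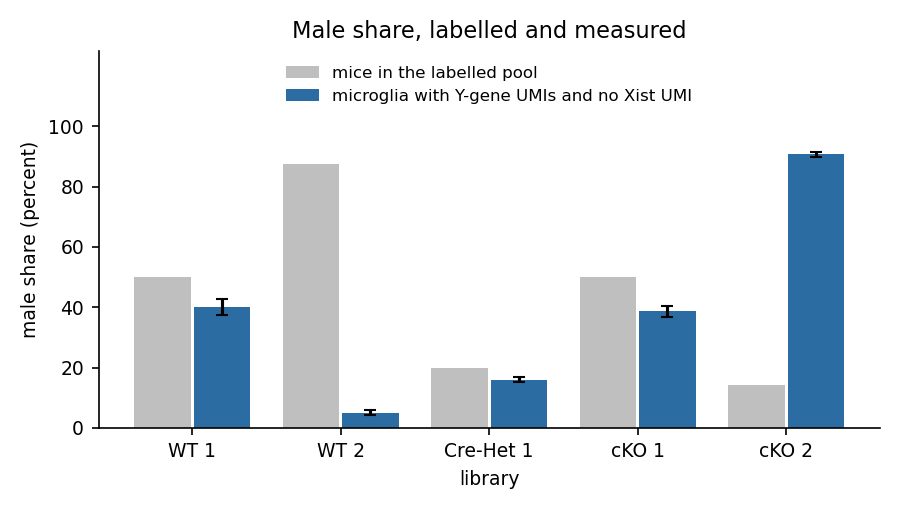
Bars give, per library, the percent of male mice in the labelled pool (grey) and the percent of male cells among microglia with sex-specific UMIs (blue), with 95% Clopper-Pearson intervals. In WT 2 the measured share was 5.05% beside a label of 87.5%, and in cKO 2 it was 90.7% beside 14.3%.

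In the control libraries, microglia with and without a Gabbr1 UMI differed in 5 of 9644 genes. Zfp277, a zinc finger gene, was higher by 0.59 in cells with the UMI, and the haemoglobin genes Hbb-bs (-2.42), Hba-a1 (-2.80), Hba-a2 (-2.85) and Hbb-bt (-2.83) were lower, named here because the count is small. Splits by 20 random genes found in a like share of cells gave a median of 4 genes and at most 9, and 8 of the 20 gave at least as many. Without the Cre-Het library 0 genes passed (edgeR, 358 at an unadjusted p under 0.05), 4 without WT 1 and 7 without WT 2, and with all 5 libraries 1 did.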

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

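The tests of differences between sexes and states, of gene positions, of the Cx3cr1 ratio and of reversed labels were chosen only after the results were seen. So was the use, as tests of explanations, of the values in female and male cells, at equal depth, with the stricter filter, without single libraries and between cKO and Cre-Het, although these settings and comparisons were set in advance.

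The change of cKO against WT differed between male and female cells for Hbb-bs, a haemoglobin gene, by 6.07 on the log2 scale. It differed between the larger clusters of the clustering centred by library, cluster 2 against cluster 1, for Xist (0.28), Fcrls (0.16), Plk4 (-1.09), Tmsb4x (-0.11), G730003C15Rik (3.49) and Gm26737 (2.28), each past the threshold of edgeR's test of the difference itself.

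The first pattern weighed is the rise of all 25 interferon-response genes in cKO against WT, with a median log2 fold change of 3.23. Sex of the pooled mice as the whole cause is argued against by the lower of the medians in female and male cells alone, 3.17. Depth and cell number are argued against by the median at equal cells and UMIs per library, 2.78. The Cre allele, or anything else the Cre-carrying libraries share, may account for part of the rise, since 23 of the genes also rose in Cre-Het. As the whole cause it cannot be told apart from a further part that comes with the receptor alleles, because 20 of the 25 genes passed between cKO and Cre-Het, with 13 without cKO 1 and 12 without cKO 2, but Cre-Het is a single library. Loss of the receptor, which the design names, therefore stays open as a hypothesis.

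The second pattern is the 402 genes at which Cre-Het lay apart from both other groups, 247 higher and 155 lower, such as Nrp1, Spint1 and Gcm1. The Cre-Het cells that the stricter filter removes are argued against as the whole cause. Under that filter the fold changes had a median ratio of 0.83 to their main values (quartiles 0.741 to 0.942). Those cells may be part of the cause, since 143 of the 402 still passed between Cre-Het and WT, as the median size fell from 0.62 to 0.52 and the median SE went from 0.10 to 0.11. The genes were chosen in the same library, so the ratio cannot show lower RNA quality shared by all its cells. A few linked segments of another strain as the source of most of the genes are argued against by position, since 187 of 394 autosomal genes had another within 1 Mb, beside a mean of 182 and a highest of 225 in 10000 permutations (permutation p = 0.347). For the genes apart by over 2-fold this cannot be told apart, because neighbours were in excess over all genes (27 of 83, beside a mean of 11.5, permutation p = 0.0011) but past no threshold without gene families (8 of 51, beside 4.57, permutation p = 0.171). Lower RNA quality of the whole Cre-Het library, a strain difference spread over the genome, the genotype and the single pool itself stay open, untested.

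The third pattern is the male share of the cells against the labelled pools of WT 2 and cKO 2. An exchange of these libraries as a whole is argued against by Cx3cr1, whose CPM in WT 2 was 2.26 times that in cKO 2, as the labelled genotypes would give, with Cre in place of 1 Cx3cr1 allele in cKO. Female and male numbers reversed in the labels of these libraries may be the source, since the gaps between measured and labelled share, 82.5 and 76.4 points as labelled, shrank to at most 7.45 points when reversed, within the largest gap of the other libraries, 11.4 points. This does not tell a reversal apart from pool numbers exchanged between the libraries. The 14.3% labelled for cKO 2 lies near the 5.05% measured in WT 2. Likewise, the 87.5% labelled for WT 2 lies near the 90.7% measured in cKO 2. No biological explanation of this pattern was tested.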

How the results depend on the processing

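Alternatives that left out state or low-UMI clusters or used the measured male share, the tests within clusters of the centred clustering and the dependence on state or sex were chosen only after the results were seen.

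For cKO against WT (410 genes changed), no expression filter gave 1243, the largest cluster alone 11, equal depth 196, female cells 135, male cells 134, no state clusters 131, the labelled male share 144, the measured male share 106 and pooled controls 9, and leaving out single libraries 224 to 441. For cKO against Cre-Het (1842) these were 3242 with no filter, 1 in the largest cluster, 581 with the stricter cell filter, 1024 at equal depth, 452 in female and 643 in male cells, 105 with the measured male share, and 242 to 2693 without single libraries. For Cre-Het against WT (600) they were 1998, 1, 259, 381, 198, 179, 63 with the labelled and 327 with the measured male share, and 254 to 766 without single libraries. For genes changed the same way against both (214) they were 704, 0, 116, 80, 35, 56, 46 without state clusters, 80 with the labelled and 24 with the measured male share, and 52 to 281 without single libraries. The filter alternative tests more genes, and the largest cluster holds 44 cells of WT 1 and 48 of Cre-Het. For the others the cause was not tested. The labelled male share, 87.5% in WT 2 and 14.3% in cKO 2, goes against the measured 5.05% and 90.7%. Counts with the labelled share therefore do not show the result after adjustment for sex. DESeq2, its size factors, all cells, kept doublets and no low-UMI clusters stayed within 1.5 times for each of these counts, with 515, 413, 363, 425 and 446 genes for cKO against WT.

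Whether the same-numbered WT and cKO libraries form pairs was not settled. Their deviations correlated at 0.0904, which cannot show that they are unpaired, so the replicate block is given here alone. With the block 505 genes changed in cKO against WT, beside 434 in the same libraries without it. Within the 3 clusters centred by library, the block gave 368, 243 and 188 genes in place of 163, 100 and 9. In the same libraries without the block these were 131, 94 and 8. No paired analysis was possible for comparisons with Cre-Het because the label of its 1 library gives no replicate number.

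Lists called by camera numbered 17 for cKO against WT (14 higher, 3 lower), 18 for cKO against Cre-Het (12 and 6) and 13 for Cre-Het against WT (9 and 4). These counts include state lists that repeat genes of another called list. An estimated correlation left 0, 0 and 0, and fry 4, 3 and 0. Those kept by fry in cKO against WT were the interferon-response, NF-kB, interferon-responsive and chemokine-rich lists. In cKO against Cre-Het they were the NF-kB, chemokine-rich and ribosomal protein lists. Within the 3 clusters, leaving out single libraries gave 86 to 270, 84 to 245 and 8 to 66 genes, and equal depth 56 in cluster 1 and 19 in cluster 3. For cells with against without a Gabbr1 UMI (5), single libraries left out gave 0 to 7 genes and all 5 libraries 1. Genes dependent on state numbered 6, and 8 with no expression filter.

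For the share of microglia with a Gabbr2 UMI, cKO minus WT, percentage points were -0.00084 as reported, turned to 0.0132 without thinning, 0.00824 at 1000 UMIs, and lay between -0.0285 and 0.0269 without single libraries, on at most 3 thinned cells per library. For the share of microglia with a Gabbr1 UMI, cKO minus WT, percentage points were -1.93 as reported, -1.23 at 1000 UMIs, -0.761 without WT 2, -3.10 without WT 1, -2.53 without cKO 1 and -1.33 without cKO 2. In the largest cluster these log2 fold changes turned: Hist1h2ae to -0.32 in cKO against WT, Gabbr1 to 0.28, Cx3cr1 to 0.20 and Csmd3 to 8.75 in cKO against Cre-Het, and Gabbr1 to -0.66, Ccl5 to -7.66 and H2-Q7 to -0.75 in Cre-Het against WT. Cx3cr1 in cKO against Cre-Het also turned to 0.11 with the stricter filter, 0.033 with the measured male share, and lay between -0.14 and 0.052 without single libraries. The turned values above and the counts below cover Gabbr1, Cx3cr1, the reported genes with the largest changes and those with the smallest p against both control groups. Genes named only as members of a list, some of them near the threshold, are not covered. Of 562 values of 27 such genes in cKO against WT, 480 kept direction and side of the threshold, 79 lost the call, 2 gained it and 1 turned. Of 537 values of 30 genes in cKO against Cre-Het these were 476, 55, 0 and 6, and of 374 values of 21 genes in Cre-Het against WT 329, 42, 0 and 3.

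Depth limits Gabbr1 and Gabbr2, found in few thinned cells, and at most 2 libraries per group limit every test. Spread is assumed equal for the single Cre-Het library, shares of microglia in each state were not compared, so other clustering resolutions for them were not run, and sex, pool and genotype are not balanced between the groups.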

Other observations

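The tests in this part, except those of preset lists, were chosen only after the results were seen.

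No test of genes near the altered loci passed the threshold. Within 10 Mb on each side of Gabbr1 or Cx3cr1, 10 tests of called against other genes gave a smallest p of 0.0546 (adjusted p = 0.546, Fisher's exact test), for cKO against WT around Gabbr1. There 15 of 283 tested genes had changed, 5.30%, against 3.10% elsewhere, among them Cdkn1a, H2-K1, H2-D1, Tap1, C4b and Tnf.

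Some preset lists showed single changes in cKO against Cre-Het or Cre-Het against WT without a call of the list. In antigen presentation 1 of 20 genes rose and 5 fell in cKO against Cre-Het. The class II gene H2-Ab1 was at 1.16, while H2-DMb1 (-2.12), H2-Q7 (-1.35) and the costimulatory gene Cd80 (-0.96) were lower. Among neurotransmitter receptors the adenosine receptor Adora3 (-0.52), the purinergic receptor P2rx7 (-0.42) and Gabbr1 (-0.58) fell in cKO against Cre-Het, and P2ry14 rose by 2.02. Of 32 lysosomal genes 3 rose in Cre-Het against WT, Ctsl (0.67), Man2b1 (0.41) and Ctsh (0.52). In lipid handling Lpl, lipoprotein lipase, rose by 1.81 in Cre-Het against WT and Scd2, a fatty acid desaturase, fell by 0.58. Apoe, the main lipid carrier of the brain, stood at 3342 and 4779 CPM in the WT libraries, 1982 in Cre-Het and 2403 and 1653 in the cKO libraries, and cKO against WT did not pass the threshold (SE 0.21 on the log2 scale, adjusted p = 0.0588, edgeR).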
